A study of Saccharomyces cerevisiae with 23 samples.

How the data were processed

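Total RNA from budding yeast (Saccharomyces cerevisiae) was measured on 2-colour Agilent gene expression arrays. The strain was a haploid laboratory strain, BY4741, that lacks PDR5, the gene of a plasma membrane drug efflux pump. Cultures grew in synthetic complete medium with 2% glucose and, during the treatment, 0.25 mM EDTA, a chelator of divalent metals. They received 5 µg/mL of a statin (an inhibitor of HMG-CoA reductase, the enzyme that makes mevalonate on the way to sterols), 1 mM CuSO4, 2 mM ZnSO4, or a statin with either metal, and all held 0.1% DMSO. Statin cultures had also been grown with the statin before the treatment. Per the labels, they were collected at a nominal OD600 of 0.4, against 0.8 for cultures without statin. Their preculture OD600 was 0.09, against 0.01. The statin and these densities therefore changed together in every comparison with against without statin, and the interactions compare metal effects across the same difference. The labels do not name the statin.

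The 23 arrays hold 17 biological samples in 6 groups, with 3 biological replicates per group except statin with ZnSO4, which has 2 (replicates 2 and 3; replicate 1 was not analysed here). Groups and replicate numbers were taken from the sample labels. For 6 biological samples, RNA was hybridised on a pair of arrays. On every array the sample carried Cy3 and a reference, a pool of RNA from all 6 conditions, carried Cy5, with no dye swap. Dye bias of a probe is therefore the same on every array and cancels between groups. Pairs of arrays of different samples correlated down to r = -0.56 over genes; the direction of the ratios was kept, because the labels state the dyes and the reference contains each condition.

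The authors scanned the arrays and extracted spot values with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The deposited scanner files hold, for each spot and channel, the intensity as a median over pixels, the median local background intensity, the processed signal after the program's background subtraction and dye normalization, and quality marks, per the file headers. The log10 ratio of red over green in those files and the authors' deposited value table hold one quantity: the table's log10 values are the scanner log10 ratio with its sign turned (sample over reference), with differences of at most 5e-06. The column medians of the table lay between 0 and 0.00326, so it had been centred by the dye normalization and by nothing further that could be seen.

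Each array had 12512 spots of 6256 probes, 1 probe per gene and 2 spots per probe, and 536 control spots. Median intensities and median background intensities were read, background was corrected with the normexp method (offset 50) on all spots, control spots were given weight 0, outlier-marked spots were set to missing, and the log ratios were normalized by loess within each array. The design written beforehand named mean intensities; the files given hold median intensities, and these were used in their place. Ratios were turned to log2 sample over reference, spots of a probe were averaged, and arrays of one biological sample were averaged. A gene was tested if both spots of its probe were well above background in the sample channel on every array of at least 1 group, which kept 5606 genes and left out 650. Among tested genes and samples, 6 values were missing. No spot was saturated. Gene names follow the systematic names in the files, of which 5756 of 6256 matched the reference table of assembly R64; the other 500 kept the name in the files. The table served for names only, and no coordinates are given, because the files use another genome build (sacCer1). Near-identical genes, such as CUP1-1 and CUP1-2 and many pairs of ribosomal protein genes, can share signal on one probe.

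Samples on the first slide (7 arrays) had 98.4 to 98.8% of their spots well above background, those on the second (8 arrays) 95.7 to 97.4% and those on the third (8 arrays) 77.1 to 89.9%. The median sample signal of an array was 913.5 to 2999 on the scanner's scale. Duplicate arrays of one biological sample correlated at r = 0.944 to 0.993 over genes, with an SD of their log2 difference of 0.06 to 0.17. The number of biological samples, 2 or 3 per group, limits the precision.

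All groups were fitted together in limma 3.58.1 (R 4.3.3; the data.table package, version 1.17.8, for reading), with 11 residual degrees of freedom and moderated variances. The comparisons were statin, CuSO4 and ZnSO4 each against untreated, statin with either metal against statin, statin with either metal against that metal, and the interaction of statin with each metal, which is the effect of the metal with statin minus its effect without. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 5606 genes (two-sided). In the text, a value after ± is the standard error of limma's fit unless SD is written, and adjusted p values are those of limma's test or, for gene lists, of limma's camera.

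The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The 24 lists were: mevalonate pathway, ergosterol branch, sterol uptake and anaerobic cell wall, hypoxic genes, isoprenoid branches, fatty acid and phospholipid synthesis, copper detoxification, copper uptake, iron regulon, zinc regulon, oxidative stress defence, sulfur assimilation, heat shock and chaperones, general stress, unfolded protein response, cell wall integrity, cytosolic ribosomal proteins, ribosome biogenesis, respiratory chain, glucose-repressed genes, multidrug resistance, phosphate regulon, a-cell mating genes and alpha-cell genes. The first pair together made a list called sterol synthesis. Each list was compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the 25 lists of a comparison, and again with the correlation estimated from the data. Of 216 pairs of a list and a comparison (sterol synthesis left out), 89 passed with the preset correlation and 20 with the estimated one; the text gives the second p wherever it ended a call. Counts of members "adjusted over the list alone" adjust limma's p values over the members of that list; where none stands beside a count of a comparison with untreated, statin or a metal alone, it equalled the count over all genes.

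Named genes were, per comparison, the 8 largest rises and 8 largest falls (5 and 5 for the interactions and for statin with a metal against that metal) among called genes with a standard name, well above background on all arrays of both groups and, outside the interactions, with all replicates of one group above all of the other. To these came up to 4 members of each list that passed camera, taken by smallest adjusted p, and always HMG1, HMG2, UPC2, CUP1-1, CTR1, FET3 and ZRT1. HIS3, LEU2, MET17 and URA3, deleted or disrupted in this strain background, were left out of the named genes. Not every gene the rule takes is reported here. No gene was below background on every array of 1 group of a comparison and above it in the other.

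Replicate number, slide and scan coincided: replicate 1 of every group was on slide 1, and so on. Over pairs of samples of different groups with the same number, deviations from the group means correlated with a median r of 0.311 (33 of 40 pairs over 0.1), against -0.149 for different numbers. Every pair was over 0.1 in CuSO4 against untreated, ZnSO4 against untreated, statin with CuSO4 against statin, and statin with CuSO4 against CuSO4, so the numbers pair the samples there; they do not in statin against untreated, and statin with ZnSO4 has only 2 pairs per comparison. A fit with the replicate number as a block was made for every comparison. Counts of changed genes come from the fit without it unless the block is named. Each called gene was also compared within each slide.

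The procedure was tested on simulated data with the real spread of each gene over 5606 genes, in 10 runs with 100 genes changed per fold size. Of genes changed 2-fold, 91.9% were recovered for statin against untreated, 88.3% for statin with ZnSO4 against statin, 74.4% for the CuSO4 interaction and 72.7% for the ZnSO4 interaction; of genes changed 4-fold, 99.5, 99.2, 98 and 97%. Among called genes, 5.34, 4.29, 5.48 and 4.12% were false in those 4 comparisons. In a separate simulation of lists of 25 genes, camera found 20 of 20 shifted lists and called 0 of 460 unshifted ones. The simulated genes were independent of each other, so this does not test false calls of lists whose genes are correlated. A 4-fold brighter sample channel was read back as a median log2 ratio of 1.97.

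The alternatives were: no background subtraction, the scanner's processed signals, the authors' value table, median centring in place of loess, Aquantile or scale normalization between arrays, the sample channel alone, no filter and a stricter filter on dim probes, outlier-marked spots kept, the brightest probe per gene, the first technical array only, all arrays with the biological sample as a random block (lists then ranked by moderated t with cameraPR), only the groups compared in the fit, the replicate number or the slide as a block, an intensity trend with a robust prior, a 2-fold minimum change, an estimated correlation between list genes, and leaving out each biological sample in turn. A fit without the third slide, the comparisons of the metals with each other and a list of iron-containing proteins were added after the data were seen.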

Results

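Transcript levels of 5606 yeast genes were compared between cultures of a strain without PDR5 that received no treatment, CuSO4, ZnSO4, a statin, a statin with CuSO4, or a statin with ZnSO4. PDR5, the deleted drug efflux pump gene, was well above background on 0 of 23 arrays, and its signal was at or below percentile 6.70 of all probes on each. Of the marker genes deleted or disrupted in this strain background, HIS3 was well above background on 0 arrays, LEU2 on 2, MET17 on 15 and URA3 on 6, with signals at or below percentiles 8.02, 7.90, 9.65 and 10.2. There were 3 biological samples in each group except statin with ZnSO4, which had 2, and the groups were measured on 3, 4, 4, 3, 5 and 4 arrays in the order given. Values are log2 ratios of a sample over a reference pooled from all conditions, and differences between groups are differences of these ratios. The first slide's arrays had at least 98.4% of spots well above background, and the third slide's at most 89.9%. Because each replicate number had its own slide, every comparison was also read within slides. There, 99.03 to 100% of the called genes kept their direction, a share that calling them on the same samples makes high.

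The first principal component held 42.4% of the variance and parted the statin samples (30.6 to 36.7) from the samples without statin (-26.7 to -9.4). Samples with a statin and a metal lay between them, at 7.14 to 15.0. The next components held 24.3 and 14.5%. Across genes, which are not independent replicates, biological samples of one group correlated at r = 0.737 to 0.915 on log2 ratios to the reference, except those of statin with CuSO4. There, replicates 1 and 2 correlated at 0.273, and sulfur assimilation genes had a mean log2 ratio of -2.60 in replicate 2 against 0.20 and -0.19 in the others.

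**Figure D1:**
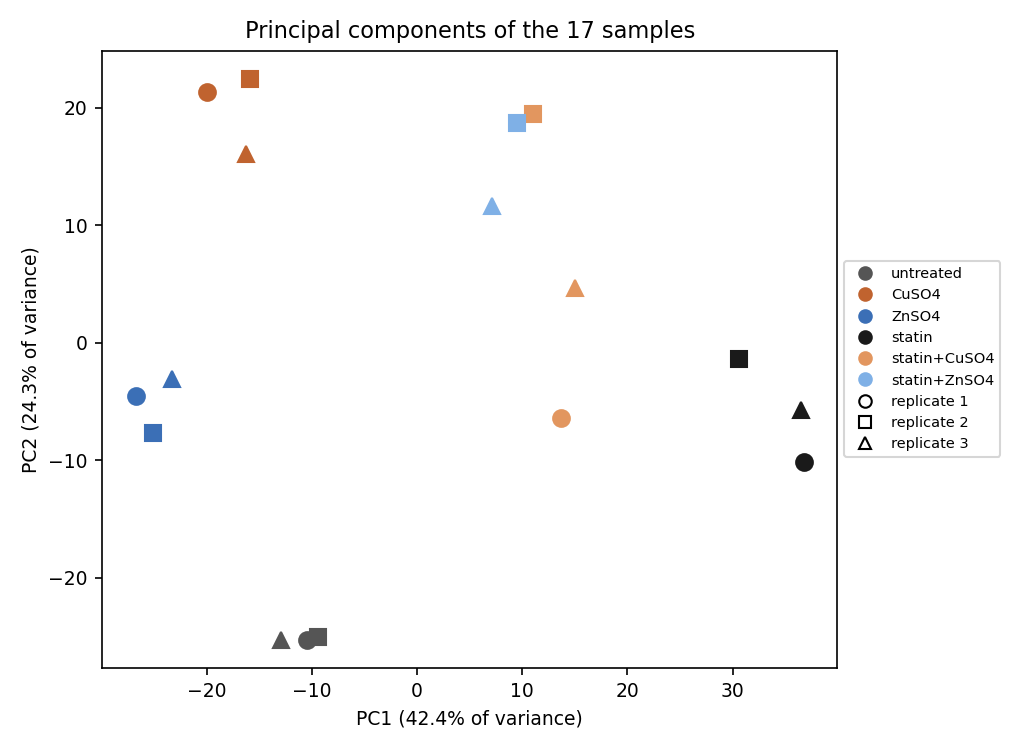
Principal components of 17 biological samples over the tested genes, with each axis in log2 units and the marker shape giving the replicate number. Statin samples lie at 30.6 to 36.7 on the first component and statin with metal samples at 7.14 to 15.0.

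Statin against untreated asked which transcripts differed in cells grown with the inhibitor of sterol synthesis. Ergosterol synthesis genes rose: 15 of 16 genes of the ergosterol branch were higher (16 adjusted over the list alone), with a median log2 change of 1.08 (camera adjusted p = 1.0e-11, adjusted p = 0.0143 with an estimated correlation). ERG3, the sterol C-5 desaturase, rose 4.37-fold (log2 2.13 ± 0.15, n = 3 per group, adjusted p = 9.6e-08), and ERG25 and ERG2, which act before it in the same branch, rose by 1.74 ± 0.14 and 1.47 ± 0.11. In the mevalonate pathway upstream, 3 of 9 genes rose (3 adjusted over the list alone) and the list did not pass (median 0.40, adjusted p = 0.227). HMG1, which encodes the main HMG-CoA reductase of aerobic cells, rose 1.47-fold (0.56 ± 0.08, adjusted p = 0.0001), whereas its paralog HMG2 had a change of -0.12 ± 0.09 (adjusted p = 0.34). Sterol synthesis as a whole had 18 of 25 genes higher (20 higher and 1 lower adjusted over the list alone) and a median of 0.88 (adjusted p = 1.2e-09, adjusted p = 0.0317 with an estimated correlation).

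Genes of sterol uptake and the anaerobic cell wall rose more: 11 of 12 were higher (11 adjusted over the list alone), with a median of 2.37 (adjusted p = 1.0e-11, adjusted p = 0.0137 with an estimated correlation). AUS1 and PDR11, transporters that take up sterols when cells cannot make them, rose 6.61-fold (2.72 ± 0.13) and 6.41-fold (2.68 ± 0.14). UPC2, the transcription factor that induces sterol genes when sterols are low, rose 5.82-fold (2.54 ± 0.20, adjusted p = 1.7e-07). The cell wall mannoproteins TIR3 and TIR4 rose by 3.27 ± 0.26 and 3.15 ± 0.18. The rises of PBI1 (43.4-fold, 5.44 ± 0.13) and HES1, an oxysterol-binding protein gene (36.5-fold, 5.19 ± 0.18), were the greatest among the named genes. SPS100, a spore wall gene, YSR3, a sphingoid base phosphatase gene, SHH3, a mitochondrial membrane protein gene, and PIR3, a cell wall gene, rose by 3.66 ± 0.51, 3.10 ± 0.15, 2.89 ± 0.43 and 2.92 ± 0.27.

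Sulfur assimilation genes fell with statin, 21 of 21 (21 adjusted over the list alone), with a median of -3.66 (adjusted p = 1.0e-11, adjusted p = 0.309 with an estimated correlation). MET3, ATP sulfurylase, fell 47.9-fold (-5.58 ± 0.98, adjusted p = 0.00042). The log2 change was -5.10 ± 0.88 for the sulfate permease SUL2 and -3.96 ± 0.71 for the cysteine transporter YCT1. It was -4.52 ± 0.88 and -4.13 ± 0.80 for the sulfite reductase subunits MET5 and MET10. The S-adenosylmethionine synthetases SAM1 and SAM2 and the S-adenosylmethionine permease SAM3 fell by 2.95 ± 0.28, 2.92 and 4.06 ± 0.36. ARG1, of arginine synthesis, fell 18.6-fold (-4.22 ± 0.29), and SER33, of serine synthesis, by 4.12 ± 0.68. Fatty acid and phospholipid synthesis genes fell, 10 of 14 (10 adjusted over the list alone), with a median of -0.74 (adjusted p = 4.9e-05, adjusted p = 0.107 with an estimated correlation). Among them were the elongase ELO1 (-1.98 ± 0.19), the inositol transporter ITR1 (-1.75 ± 0.23) and CHO1, phosphatidylserine synthase (-1.39 ± 0.15). Zinc regulon genes fell, 8 of 13 (8 adjusted over the list alone), with a median of -0.66 (adjusted p = 0.00107, adjusted p = 0.0317 with an estimated correlation). ZPS1, a cell surface protein gene, fell by 1.88 ± 0.20 and ZRT1, the high-affinity zinc transporter, by 0.70 ± 0.16.

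Cell wall integrity genes rose, 12 of 15 (12 adjusted over the list alone, median 0.95, adjusted p = 5.3e-08, adjusted p = 0.0977 with an estimated correlation), with PRM5 at 2.45 ± 0.13 and the chitin synthase CHS1 at 1.63 ± 0.10. Heat shock and chaperone genes rose, 14 of 22 (14 adjusted over the list alone, median 0.56, adjusted p = 1.6e-05, adjusted p = 0.364 with an estimated correlation), with the disaggregase HSP104 at 1.21 ± 0.18. Ribosomal protein genes rose, 51 of 137 (51 adjusted over the list alone, median 0.53, adjusted p = 3.5e-09, adjusted p = 0.581 with an estimated correlation). So did ribosome biogenesis genes, 17 of 28 (21 adjusted over the list alone, median 0.62, adjusted p = 1.8e-06, adjusted p = 0.567 with an estimated correlation). Respiratory chain genes fell, 20 of 28 (21 adjusted over the list alone, median -0.54, adjusted p = 1.8e-06, adjusted p = 0.26 with an estimated correlation), with COR1 and CYT1 of complex III at -0.80 ± 0.12 and -0.91 ± 0.15. Unfolded protein response genes fell, 5 of 11 (6 adjusted over the list alone, median -0.70, adjusted p = 0.0152, adjusted p = 0.567 with an estimated correlation), with the chaperone cofactor SIL1 at -1.25 ± 0.29.

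Of the other lists, none passed in this comparison. Copper detoxification had a median of 0.42 with 2 of 4 genes higher (adjusted p = 0.514), general stress 0.29 with 4 of 21 higher and 3 lower (0.618). The iron regulon had a median of 0.10 with 6 of 25 higher and 2 lower (0.284), and multidrug resistance 0.09 with 4 of 12 higher and 2 lower (0.26). Oxidative stress defence had a median of -0.09 with 1 of 20 genes higher and 5 lower (adjusted p = 0.224), alpha-cell genes -0.15 with 0 of 3 changed (0.618), and the phosphate regulon -0.31 with 3 of 14 higher and 6 lower (3 and 7 adjusted over the list alone, 0.152). Medians and means differed in sign, with no list past the test, for copper uptake (median -0.31, mean 0.02, adjusted p = 0.514), hypoxic genes (-0.06 and 0.05, 0.994), isoprenoid branches (-0.13 and 0.01, 0.808), glucose-repressed genes (0.03 and -0.14, 0.92) and a-cell mating genes (0.03 and -0.02, 0.92). FET3, the iron uptake oxidase, and CTR1, the high-affinity copper transporter, had changes of 0.06 ± 0.18 and -0.09 ± 0.25. CUP1-1, the copper metallothionein, was higher by 0.80 ± 0.29 (adjusted p = 0.042), a call lost without untreated replicate 1 (0.71, adjusted p = 0.125) or 2 (0.60, 0.163) or statin replicate 1 (0.74, 0.109) or 3 (0.69, 0.14). In all, 2065 genes changed, 1009 higher and 1056 lower, with 2026 of them having all replicates of one group above all of the other. Chance gives this in 10% of genes not chosen by the test, so for called genes the count only describes them, here and in the other comparisons.

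**Figure D2:**
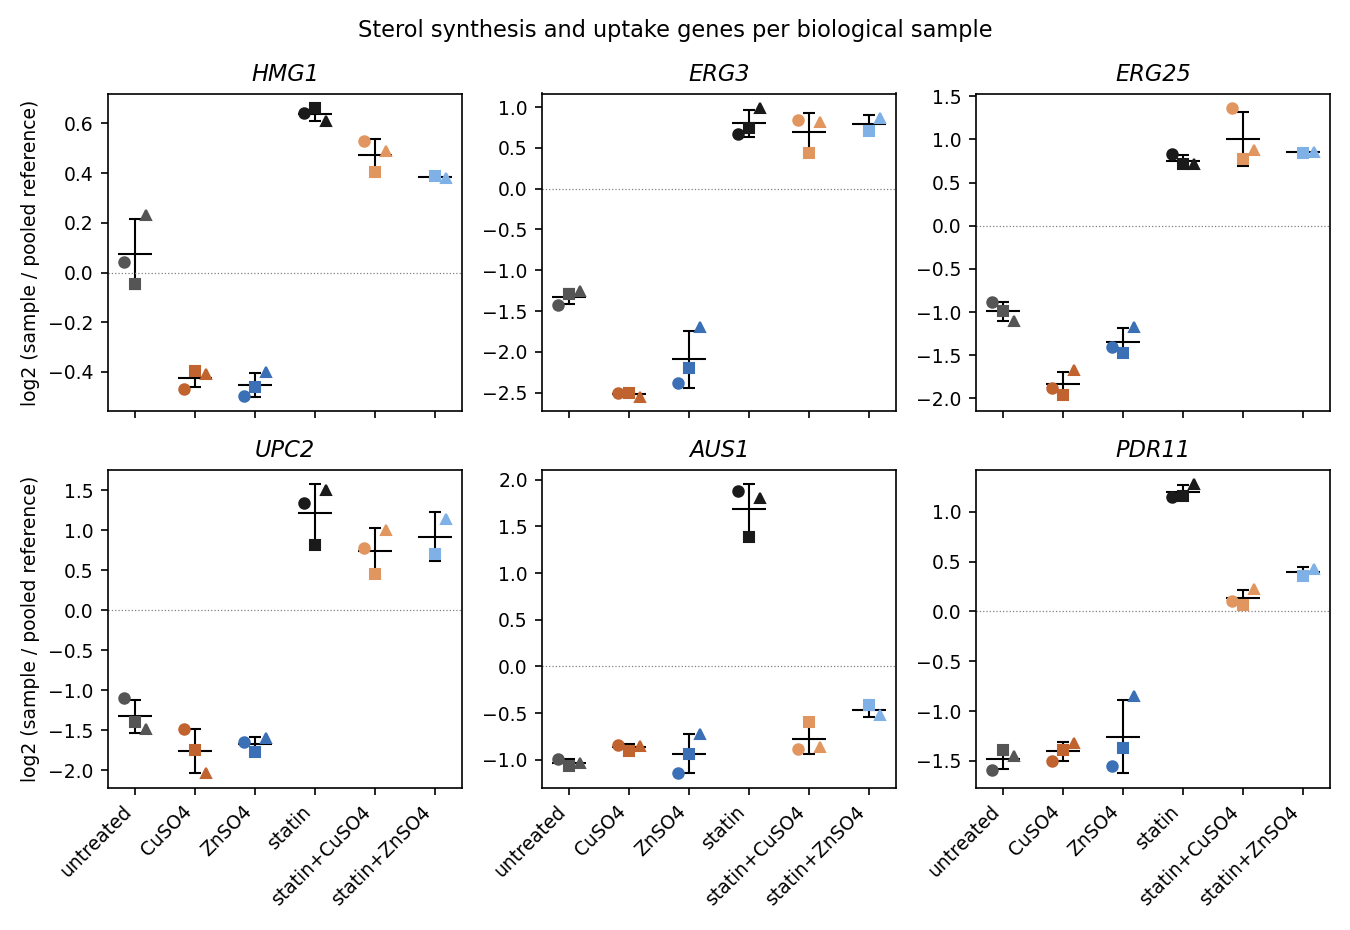
Log2 sample over reference of HMG1, ERG3, ERG25, UPC2, AUS1 and PDR11 in the 6 groups, with 1 point per biological sample and bars for the mean ± SD. AUS1 stands at 1.69 with statin and at -0.78 and -0.47 when CuSO4 or ZnSO4 is added to it.

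CuSO4 against untreated asked what copper did in cells without statin. The metallothionein CUP1-1 rose 43.9-fold (5.46 ± 0.29, n = 3 per group, adjusted p = 4.9e-09) and the copper transporter CTR1 fell 15-fold (-3.91 ± 0.25). All 25 measured iron regulon genes fell (25 adjusted over the list alone), with a median of -1.82 (adjusted p = 5.0e-25, adjusted p = 0.0192 with an estimated correlation). Among them, ARN2, a siderophore transporter, fell 36.2-fold (-5.18 ± 0.20), FIT1, a siderophore-binding mannoprotein, 19.2-fold (-4.26 ± 0.17), and FET3 by 1.26 ± 0.18. The ferric reductases FRE1 and FRE2 were at -4.27 ± 0.23 and -3.46 ± 0.17. LEU1, an iron-sulfur enzyme of leucine synthesis, rose 20.8-fold (4.38 ± 0.26), and ILV3, an iron-sulfur enzyme of branched-chain amino acid synthesis, by 2.45 ± 0.23.

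Copper detoxification passed as a list on 2 of 4 genes, the near-identical CUP1-1 and CUP1-2 (median 2.86, adjusted p = 0.0166, adjusted p = 0.435 with an estimated correlation, adjusted p = 0.0547 with only these groups in the fit). Its members CRS5, a second metallothionein, and SOD1, superoxide dismutase, had changes of -0.16 (adjusted p = 0.32) and 0.26 (0.42). Copper uptake genes fell, 4 of 6 (median -0.64, adjusted p = 0.00188, adjusted p = 0.233 with an estimated correlation). Ribosomal protein genes rose, 135 of 137 (136 higher and 1 lower adjusted over the list alone, median 1.51, adjusted p = 4.8e-45, adjusted p = 0.233 with an estimated correlation), with RPL24A at 1.96 ± 0.20. Ribosome biogenesis genes rose, 28 of 28 (28 adjusted over the list alone, median 1.53, adjusted p = 3.2e-19, adjusted p = 0.233 with an estimated correlation), with the nucleolar protein NSR1 at 2.36 ± 0.26. Respiratory chain genes rose, 25 of 28 (26 adjusted over the list alone, median 0.79, adjusted p = 2.0e-14, adjusted p = 0.122 with an estimated correlation), with the succinate dehydrogenase subunit SDH2 at 1.88 ± 0.17. Sulfur assimilation genes fell, 7 of 21 (10 adjusted over the list alone, median -1.60, adjusted p = 0.000505, adjusted p = 0.787 with an estimated correlation). The sulfate permease SUL1 fell 45.3-fold (-5.50 ± 0.99) and CYS3, of cysteine synthesis, by 1.89 ± 0.47. General stress genes fell, 12 of 21 with 2 higher (median -0.59, adjusted p = 0.0147, adjusted p = 0.813 with an estimated correlation). The glycogen synthesis genes GLC3 and GSY1 were at -1.41 ± 0.17 and -1.26, and the catalase CTT1 the other way at 2.12 ± 0.31.

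Sterol synthesis did not pass with CuSO4 (median -0.24, 3 of 25 genes higher and 9 lower, adjusted p = 0.353), and the ergosterol branch had 2 of 16 genes higher and 8 lower (3 and 8 adjusted over the list alone, median -0.29, adjusted p = 0.154). HMG1 fell by 0.50 ± 0.08 (adjusted p = 0.00029), and UPC2 was at -0.43 ± 0.20 (adjusted p = 0.1, and 0.047 with a replicate block). In all, 1939 genes changed, 1011 higher and 928 lower, of which 1879 had non-overlapping replicates (10% by chance).

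ZnSO4 against untreated asked the same of zinc. ZRT1, the high-affinity zinc transporter, fell 32-fold (-5.00 ± 0.16, n = 3 per group, adjusted p = 2.8e-11), and the zinc transporters ZRT2, of the plasma membrane, and ZRT3, of the vacuole, fell by 2.06 ± 0.16 and 2.08 ± 0.13. The zinc regulon had 6 of 13 genes lower and 1 higher, with a median of only -0.17 (adjusted p = 2.95e-06, adjusted p = 0.00883 with an estimated correlation), and its median was -0.27 without untreated replicate 2, -0.10 without untreated replicate 3 and -0.31 without ZnSO4 replicate 3. Iron regulon genes fell here too, 22 of 25 with 1 higher (23 lower and 1 higher adjusted over the list alone), with a median of -1.53 (adjusted p = 3.0e-25, adjusted p = 0.00883 with an estimated correlation). FIT1 fell 16.1-fold (-4.01 ± 0.17), and ARN2, FIT3 and FET3 by 3.06, 2.76 and 1.76 ± 0.18. Copper uptake genes fell, 3 of 6 with 1 higher (median -0.36, adjusted p = 0.0196, adjusted p = 0.445 with an estimated correlation), with CTR1 6.71-fold lower (-2.75 ± 0.25).

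LEU1 rose 14.1-fold with ZnSO4 (3.82 ± 0.26), and BIO2, an iron-sulfur enzyme of biotin synthesis, 8.3-fold (3.05 ± 0.28), with the biotin genes BIO3, BIO4 and BIO5 at 2.95, 1.90 and 2.95. Respiratory chain genes rose, 15 of 28 (17 adjusted over the list alone, median 0.61, adjusted p = 5.5e-13, adjusted p = 0.107 with an estimated correlation), with SDH4 at 1.48 ± 0.16. Ribosome biogenesis genes rose, 23 of 28 (26 adjusted over the list alone, median 0.86, adjusted p = 3.7e-15, adjusted p = 0.34 with an estimated correlation), with RRP12 at 1.15. Ribosomal protein genes passed as a list on a small median of 0.22 with 1 of 137 genes called and 0 adjusted over the list alone (adjusted p = 0.000706, adjusted p = 0.851 with an estimated correlation). This call was lost without untreated replicate 2 (0.14, adjusted p = 0.0757) or ZnSO4 replicate 1 (0.15, 0.0611), and the median was 0.34 without ZnSO4 replicate 2. General stress genes fell, 12 of 21 with 1 higher (16 lower and 1 higher adjusted over the list alone, median -0.93, adjusted p = 1.2e-10, adjusted p = 0.34 with an estimated correlation). Heat shock genes fell, 8 of 22 (10 adjusted over the list alone, median -0.48, adjusted p = 2.1e-05, adjusted p = 0.445 with an estimated correlation). GLC3 was at -1.96 ± 0.17 and HSP104 at -1.37 ± 0.18.

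Sterol synthesis did not pass with ZnSO4 (median -0.02, 4 of 25 genes higher and 4 lower, 5 and 6 adjusted over the list alone, adjusted p = 0.637). HMG1 fell by 0.53 ± 0.08 (adjusted p = 0.00048), UPC2 was at -0.35 (adjusted p = 0.27), and CUP1-1 was at 0.70 ± 0.29 (adjusted p = 0.12, and 0.015 with a replicate block). In all, 930 genes changed, 494 higher and 436 lower, of which 921 had non-overlapping replicates (10% by chance), and 610 changed without untreated replicate 1.

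The genes called with CuSO4 and with ZnSO4 overlapped. In the same direction 711 genes were called in both, 379 higher and 332 lower, against 161 from n1 × n2 / N, and 14 were called in opposite directions against 160. Because both comparisons used the same 3 untreated samples, 100 simulations of unchanged groups against shared controls were made. They called too few genes to overlap (highest value 0), so the simulated count is no reference for long lists of called genes. The covariance of the log2 changes was 0.169 beside a simulated 0.0163, and r over genes was 0.643 beside 0.501. The simulated covariance is what shared controls gave in unchanged groups, and 0.153 lay beyond it. The 3 controls were not split between the comparisons, so whether part of that excess also comes from them was not tested.

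Statin with CuSO4 against statin asked what copper did to statin-treated cells. The sterol uptake and anaerobic cell wall genes that statin raised were lower, 7 of 12 (9 adjusted over the list alone), with a median of -0.99 (adjusted p = 3.9e-09, adjusted p = 0.0127 with an estimated correlation). AUS1 fell 5.55-fold (-2.47 ± 0.13, n = 3 per group, adjusted p = 7.5e-09), PDR11 2.1-fold (-1.07 ± 0.14), and TIR1 and TIR4 by 2.99 ± 0.17 and 1.87 ± 0.18. Sterol synthesis genes did not fall: 7 of 25 were higher and 2 lower (10 and 2 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.0197, adjusted p = 0.392 with an estimated correlation). That call was lost without statin replicate 1 (0.06, adjusted p = 0.0743), and the median was 0.23 without statin replicate 2 and 0.21 without statin with CuSO4 replicate 1. HMG1 and UPC2 were at -0.16 (adjusted p = 0.23) and -0.47 ± 0.20 (0.12; 0.0265 without statin replicate 2).

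Iron regulon genes fell, 23 of 25 (23 adjusted over the list alone, median -2.17, adjusted p = 7.8e-38, adjusted p = 0.00338 with an estimated correlation). FIT1 was 29.1-fold lower (-4.86 ± 0.17), the siderophore transporters ARN2 and ENB1 at -4.92 ± 0.20 and -4.81 ± 0.19, and FET3 at -2.20 ± 0.18. Respiratory chain genes rose, 28 of 28 (28 adjusted over the list alone, median 1.59, adjusted p = 3.3e-37, adjusted p = 0.00402 with an estimated correlation), with SDH4 at 2.78 ± 0.16, SDH3 at 2.67 ± 0.15 and COR1 at 1.96 ± 0.12. CUP1-1 rose 34.8-fold (5.12 ± 0.29), LEU1 24.7-fold (4.63 ± 0.26) and CCP1, mitochondrial cytochrome c peroxidase, 11.1-fold (3.47 ± 0.20). CTR1 fell 14-fold (-3.81 ± 0.25), ZRT1 1.97-fold (-0.98 ± 0.16) and SPS100 11.9-fold (-3.58 ± 0.51). Copper detoxification genes rose, 2 of 4 (3 adjusted over the list alone, median 2.89, adjusted p = 0.000283, adjusted p = 0.177 with an estimated correlation). Copper uptake genes fell, 4 of 6 (5 lower and 1 higher adjusted over the list alone, median -1.83, adjusted p = 2.3e-05, adjusted p = 0.0853 with an estimated correlation).

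Sulfur assimilation genes rose against statin, 19 of 21 (21 adjusted over the list alone, median 2.67, adjusted p = 6.5e-12, adjusted p = 0.389 with an estimated correlation). MET5 rose by 4.21 ± 0.88, MET6, methionine synthase, by 2.75 ± 0.50 and SAM1 by 1.70 ± 0.28. The list's medians within slides were 3.67, 0.82 and 3.37, the middle one from statin with CuSO4 replicate 2. MET3 rose by 3.79 ± 0.98 (adjusted p = 0.013), a call lost without statin with CuSO4 replicate 1 (3.01, adjusted p = 0.0607) or 3 (3.19, 0.0709).

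Other lists passed with small medians. Oxidative stress defence rose, 5 of 20 (6 adjusted over the list alone, median 0.16, adjusted p = 0.0102, adjusted p = 0.389 with an estimated correlation), with CTT1 at 3.47 ± 0.31. Its median was 0.17 without statin with CuSO4 replicate 1 (adjusted p = 0.058) and 0.26 without replicate 2. Fatty acid and phospholipid synthesis rose, 5 of 14 with 1 lower (6 and 2 adjusted over the list alone, median 0.34, adjusted p = 0.0293, adjusted p = 0.392 with an estimated correlation), with ITR1 at 1.30 ± 0.23. The call was lost without statin replicate 1 (adjusted p = 0.0513) or 3 (0.0616) or statin with CuSO4 replicate 2 (0.124). Unfolded protein response rose on 1 of 11 genes (0 adjusted over the list alone, median 0.41, adjusted p = 0.0293, adjusted p = 0.569 with an estimated correlation). It lost the call without statin with CuSO4 replicate 2 (0.30, adjusted p = 0.227). Heat shock genes fell, 2 of 22 (median -0.25, adjusted p = 0.0245, adjusted p = 0.583 with an estimated correlation). They lost the call without statin replicate 3 (-0.18, adjusted p = 0.081) or statin with CuSO4 replicate 2 (-0.10, 0.309). Ribosomal protein genes passed downward with 0 of 137 called (median -0.21, adjusted p = 0.000956, adjusted p = 0.791 with an estimated correlation). The median was -0.65, 0.27 and -0.27 within slides, and -0.07 (0.522), -0.47 and -0.11 (0.0665) without statin with CuSO4 replicate 1, 2 or 3. With a replicate block 1 member was called lower, RPS14B (-0.64, adjusted p = 0.00442), and without statin with CuSO4 replicate 2 it was 24 members, among them RPL16B (-0.82, 0.0237), RPS0A (-0.65, 0.0198) and RPL12A (-0.79, 0.012). Ribosome biogenesis did not pass (median -0.04, adjusted p = 0.943), but passed in opposite directions without statin with CuSO4 replicate 1 (0.22, 0.0191) and without replicate 2 (-0.23, 0.011). In all, 939 genes changed, 529 higher and 410 lower, of which 901 had non-overlapping replicates (10% by chance), and 570 changed with only these groups in the fit.

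Statin with ZnSO4 against statin asked the same of zinc, with 2 biological samples against 3. AUS1 fell 4.48-fold (-2.16 ± 0.15, adjusted p = 9.8e-08), PDR11 1.75-fold (-0.81 ± 0.16) and TIR1 and TIR4 by 2.54 and 1.28. As a list, sterol uptake and anaerobic cell wall genes fell, 6 of 12 (8 adjusted over the list alone, median -0.81, adjusted p = 2.1e-06, adjusted p = 0.0371 with an estimated correlation). Sterol synthesis did not pass (median 0.11, 8 of 25 higher and 2 lower, 8 and 3 adjusted over the list alone, adjusted p = 0.0773). It passed upward without statin replicate 2 (0.18, adjusted p = 0.0326) or statin with ZnSO4 replicate 3 (0.21, 0.0202). Iron regulon genes fell, 22 of 25 (23 adjusted over the list alone, median -2.31, adjusted p = 6.5e-27, adjusted p = 0.0138 with an estimated correlation), with FIT1 26.4-fold lower (-4.72 ± 0.19). ZRT1 fell 16.1-fold (-4.01 ± 0.18), ZRT2 by 2.55 and ZRT3 by 1.79. The zinc regulon passed downward with 6 of 13 lower and 1 higher and a mean of -0.86, although its median was 0.01 (adjusted p = 0.00139, adjusted p = 0.0365 with an estimated correlation) and -0.07 to 0.01 without single samples.

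Respiratory chain genes rose, 25 of 28 (28 adjusted over the list alone, median 1.27, adjusted p = 2.1e-24, adjusted p = 0.0206 with an estimated correlation), with SDH4 at 2.41 ± 0.18. LEU1 rose 33.5-fold (5.06 ± 0.29), ARG1 14.2-fold (3.82 ± 0.33) and CCP1 10.4-fold (3.38 ± 0.22). Sulfur assimilation genes rose, 16 of 21 (19 adjusted over the list alone, median 2.17, adjusted p = 1.3e-07, adjusted p = 0.523 with an estimated correlation). Their medians were 1.26 and 3.51 on the slides of replicates 2 and 3 and 3.48 without replicate 2. MET5 at 4.08 ± 0.98 (adjusted p = 0.008) lost its call without statin with ZnSO4 replicate 3 (2.53, adjusted p = 0.163), and SAM1 rose by 1.80 ± 0.32. General stress genes fell, 12 of 21 with 1 higher (14 and 1 adjusted over the list alone, median -0.79, adjusted p = 1.5e-06, adjusted p = 0.523 with an estimated correlation). Heat shock genes fell, 7 of 22 (9 adjusted over the list alone, median -0.47, adjusted p = 6.6e-05, adjusted p = 0.523 with an estimated correlation), with HSP104 at -1.05. Copper uptake genes fell, 4 of 6 with 1 higher (median -1.45, adjusted p = 0.024, adjusted p = 0.523 with an estimated correlation). With a replicate block the median was -1.47 and the adjusted p 0.0707. Ribosome biogenesis genes rose, 14 of 28 (18 adjusted over the list alone, median 0.61, adjusted p = 2.5e-07, adjusted p = 0.523 with an estimated correlation). Ribosomal proteins passed with 0 of 137 called (median 0.19, adjusted p = 0.024, adjusted p = 0.783 with an estimated correlation). This call was lost without statin replicate 3 (0.14, adjusted p = 0.196) or statin with ZnSO4 replicate 2 (0.03, 0.826), and the median was 0.37 without replicate 3. Without statin with CuSO4 replicate 2 in the fit, 2 members were called higher.

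HMG1 was at -0.25 ± 0.09 (adjusted p = 0.067, and 0.038 with a replicate block), UPC2 at -0.30 (0.37) and CUP1-1 at 0.77 (0.11, and 0.0081 with the block). In all, 1232 genes changed, 655 higher and 577 lower, of which 1228 had non-overlapping replicates (20% by chance with 3 against 2 samples). The count was 817 without statin replicate 1, and 759 or 564 without statin with ZnSO4 replicate 2 or 3, which leaves 1 sample in that group. Genes called in the same direction with either metal added to statin numbered 710, 385 higher and 325 lower, against 104 from n1 × n2 / N. The simulated overlap was again 0 for lack of called genes. In opposite directions 0 were called, against 102. Without statin with ZnSO4 replicate 3 the overlap was 422. The covariance of the changes was 0.256 beside a simulated 0.0164, and r was 0.854 beside 0.449. Beyond what shared statin samples gave in unchanged groups, 0.240 of the covariance remained. The 3 statin samples were not split between the comparisons, so whether part of that excess also comes from them was not tested.

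**Figure D3:**
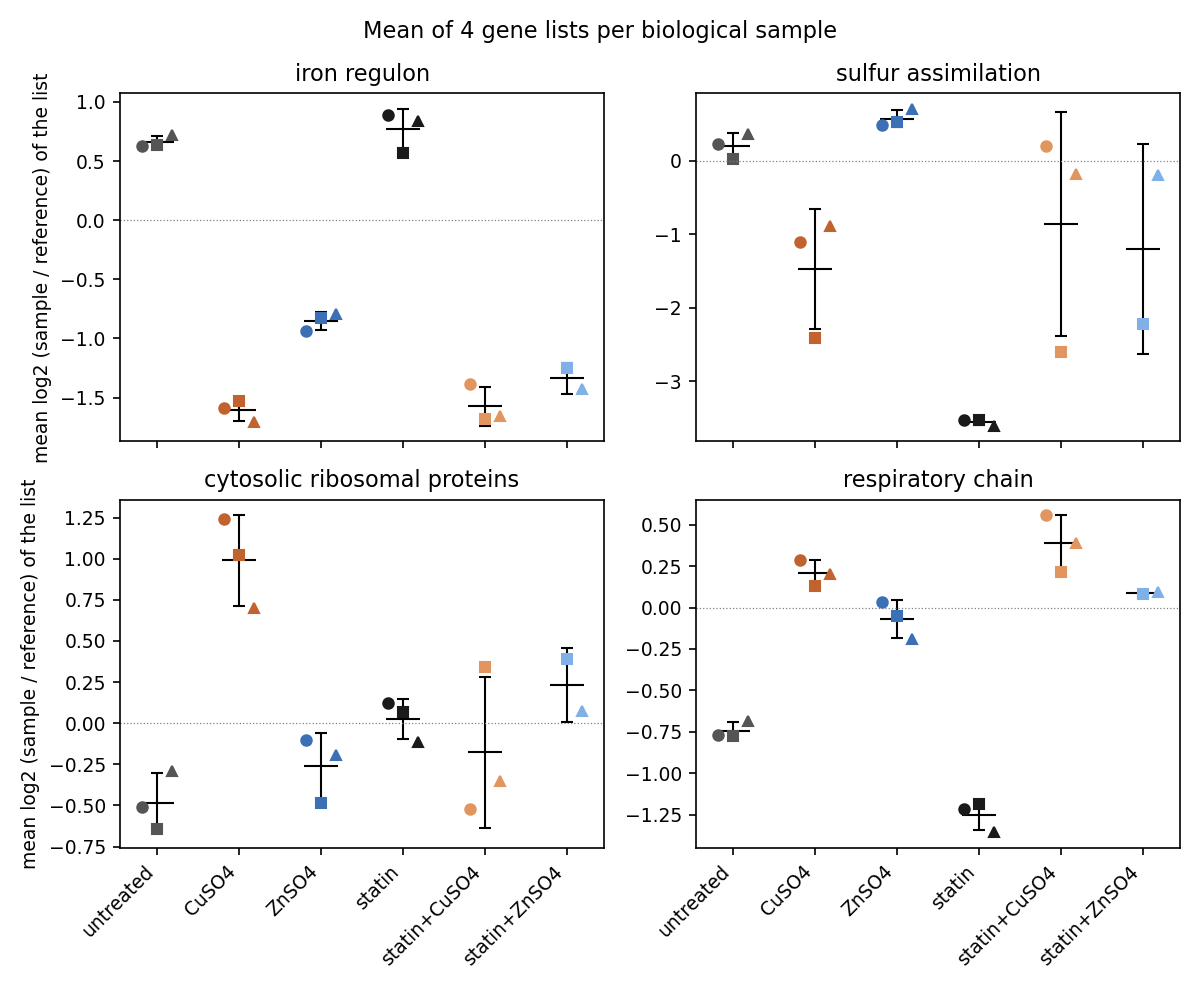
Mean log2 sample over reference of the members of gene lists in each biological sample, by group, with bars for the group mean ± SD. The lists are iron regulon, sulfur assimilation, cytosolic ribosomal proteins and respiratory chain. The iron regulon stands at 0.77 with statin and at -1.57 and -1.34 with statin and CuSO4 or ZnSO4. The respiratory chain stands at -1.25, 0.39 and 0.09 in the same groups.

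Statin with CuSO4 against CuSO4 asked what statin did in the presence of copper. All 16 ergosterol branch genes rose (16 adjusted over the list alone), with a median of 1.35 (adjusted p = 2.7e-15, adjusted p = 0.0102 with an estimated correlation). ERG3 rose 9.3-fold (3.22 ± 0.15, n = 3 per group), ERG25 by 2.84 ± 0.14 and ERG5, the sterol C-22 desaturase, by 2.49 ± 0.11. Of 25 sterol synthesis genes, 22 rose and 1 fell (median 1.20, adjusted p = 6.2e-14, adjusted p = 0.0167 with an estimated correlation). Of 9 mevalonate pathway genes, 6 rose and 1 fell (median 0.44, adjusted p = 0.0236, adjusted p = 0.309 with an estimated correlation), a call lost without statin with CuSO4 replicate 2 (0.36, adjusted p = 0.0789). HMG1 was 1.86-fold higher (0.90 ± 0.08, adjusted p = 1.6e-06). Sterol uptake and anaerobic cell wall genes rose, 9 of 12 (median 1.47, adjusted p = 4.3e-06, adjusted p = 0.044 with an estimated correlation), with PDR11 at 1.54 ± 0.14. The rise of AUS1 was nearly absent here, since its interaction with CuSO4 (-2.64) was almost as large as its rise with statin alone. UPC2 rose 5.65-fold (2.50 ± 0.20), PBI1 34-fold (5.09 ± 0.13) and HES1 31.1-fold (4.96 ± 0.18).

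Ribosomal protein genes fell with statin when copper was present, 131 of 137 (134 adjusted over the list alone, median -1.17, adjusted p = 1.4e-28, adjusted p = 0.309 with an estimated correlation), at -1.81, -0.68 and -1.04 within slides. Ribosome biogenesis genes fell, 25 of 28 (26 adjusted over the list alone, median -0.78, adjusted p = 7.5e-08, adjusted p = 0.518 with an estimated correlation). Sulfur assimilation had 0 of 21 genes called (median 0.67, adjusted p = 0.322; 1.62 and 0.0014 without statin with CuSO4 replicate 2). Zinc regulon genes fell, 7 of 13 (median -0.45, adjusted p = 0.0019, adjusted p = 0.0424 with an estimated correlation), and the median was -0.69 without CuSO4 replicate 2. ZPS1 was at -3.42 ± 0.20 and ZRT1 3.15-fold lower (-1.65 ± 0.16). Cell wall integrity genes rose, 12 of 15 with 1 lower (median 1.17, adjusted p = 4.3e-06, adjusted p = 0.191 with an estimated correlation), with the MAP kinase gene SLT2 at 1.17. Multidrug resistance genes rose, 7 of 12 with 1 lower (median 0.66, adjusted p = 0.00838, adjusted p = 0.202 with an estimated correlation). General stress genes rose, 11 of 21 (12 higher and 1 lower adjusted over the list alone, median 0.63, adjusted p = 0.0019, adjusted p = 0.543 with an estimated correlation), and the median was 0.36 without statin with CuSO4 replicate 1. Heat shock genes rose, 13 of 22 with 1 lower (14 and 1 adjusted over the list alone, median 0.40, adjusted p = 0.00651, adjusted p = 0.543 with an estimated correlation). The lysine synthesis genes LYS20 and LYS9 fell by 3.22 ± 0.26 and 3.16. In all, 2486 genes changed, 1182 higher and 1304 lower, of which 2278 had non-overlapping replicates (10% by chance).

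Statin with ZnSO4 against ZnSO4 had 2 samples against 3. All 16 ergosterol branch genes rose (16 adjusted over the list alone, median 1.25, adjusted p = 2.2e-16, adjusted p = 0.00712 with an estimated correlation), with ERG3 7.36-fold higher (2.88 ± 0.17). In all, 21 of 25 sterol synthesis genes rose (median 1.14, adjusted p = 4.4e-15, adjusted p = 0.0118 with an estimated correlation). HMG1 rose 1.79-fold (0.84 ± 0.09, adjusted p = 1.5e-05) and UPC2 6.01-fold (2.59 ± 0.22). Of 9 mevalonate pathway genes, 5 rose (median 0.72, adjusted p = 0.0153, adjusted p = 0.296 with an estimated correlation), a call lost without statin with ZnSO4 replicate 2 (0.61, adjusted p = 0.0735). Sterol uptake and anaerobic cell wall genes rose, 10 of 12 (median 1.41, adjusted p = 1.7e-08, adjusted p = 0.0158 with an estimated correlation). AUS1 rose much less than with statin alone, as its interaction with ZnSO4 (-2.26) shows. HES1 rose 24.4-fold (4.61 ± 0.20) and PBI1 20.3-fold (4.34 ± 0.15).

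Sulfur assimilation genes fell, 8 of 21 (median -1.64, adjusted p = 5.1e-05, adjusted p = 0.564 with an estimated correlation), at -2.64 and -0.84 within slides. The call was lost without statin with ZnSO4 replicate 2 (-0.81, adjusted p = 0.0735), and the median was -2.66 without replicate 3. The cysteine transporter YCT1 fell by 3.99 ± 0.80. Ribosomal protein genes rose, 33 of 137 (18 adjusted over the list alone, median 0.52, adjusted p = 4.3e-08, adjusted p = 0.653 with an estimated correlation), and the median was 0.34 without statin with ZnSO4 replicate 2. So did ribosome biogenesis genes, 8 of 28 (median 0.40, adjusted p = 0.000958, adjusted p = 0.653 with an estimated correlation). Cell wall integrity genes rose, 10 of 15 with 1 lower (11 and 2 adjusted over the list alone, median 0.90, adjusted p = 3.1e-06, adjusted p = 0.179 with an estimated correlation). Heat shock genes rose, 9 of 22 (median 0.48, adjusted p = 5.1e-05, adjusted p = 0.459 with an estimated correlation). Fatty acid and phospholipid synthesis fell, 3 of 14 (median -0.41, adjusted p = 0.0029, adjusted p = 0.296 with an estimated correlation), with ELO1 at -2.02 ± 0.21. The iron regulon passed downward with 9 of 25 lower and 2 higher (median -0.13, adjusted p = 0.00423, adjusted p = 0.462 with an estimated correlation, median -0.26 without ZnSO4 replicate 1 or statin with ZnSO4 replicate 2). The zinc regulon fell, 5 of 13 (median -0.34, adjusted p = 0.0336, adjusted p = 0.179 with an estimated correlation), a call lost without ZnSO4 replicate 3 (adjusted p = 0.0793) or statin with ZnSO4 replicate 2 (0.0729). In all, 1602 genes changed, 808 higher and 794 lower, of which 1595 had non-overlapping replicates (20% by chance), and the count was 1025 without ZnSO4 replicate 1 and 1008 or 719 without statin with ZnSO4 replicate 2 or 3.

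**Figure D4:**
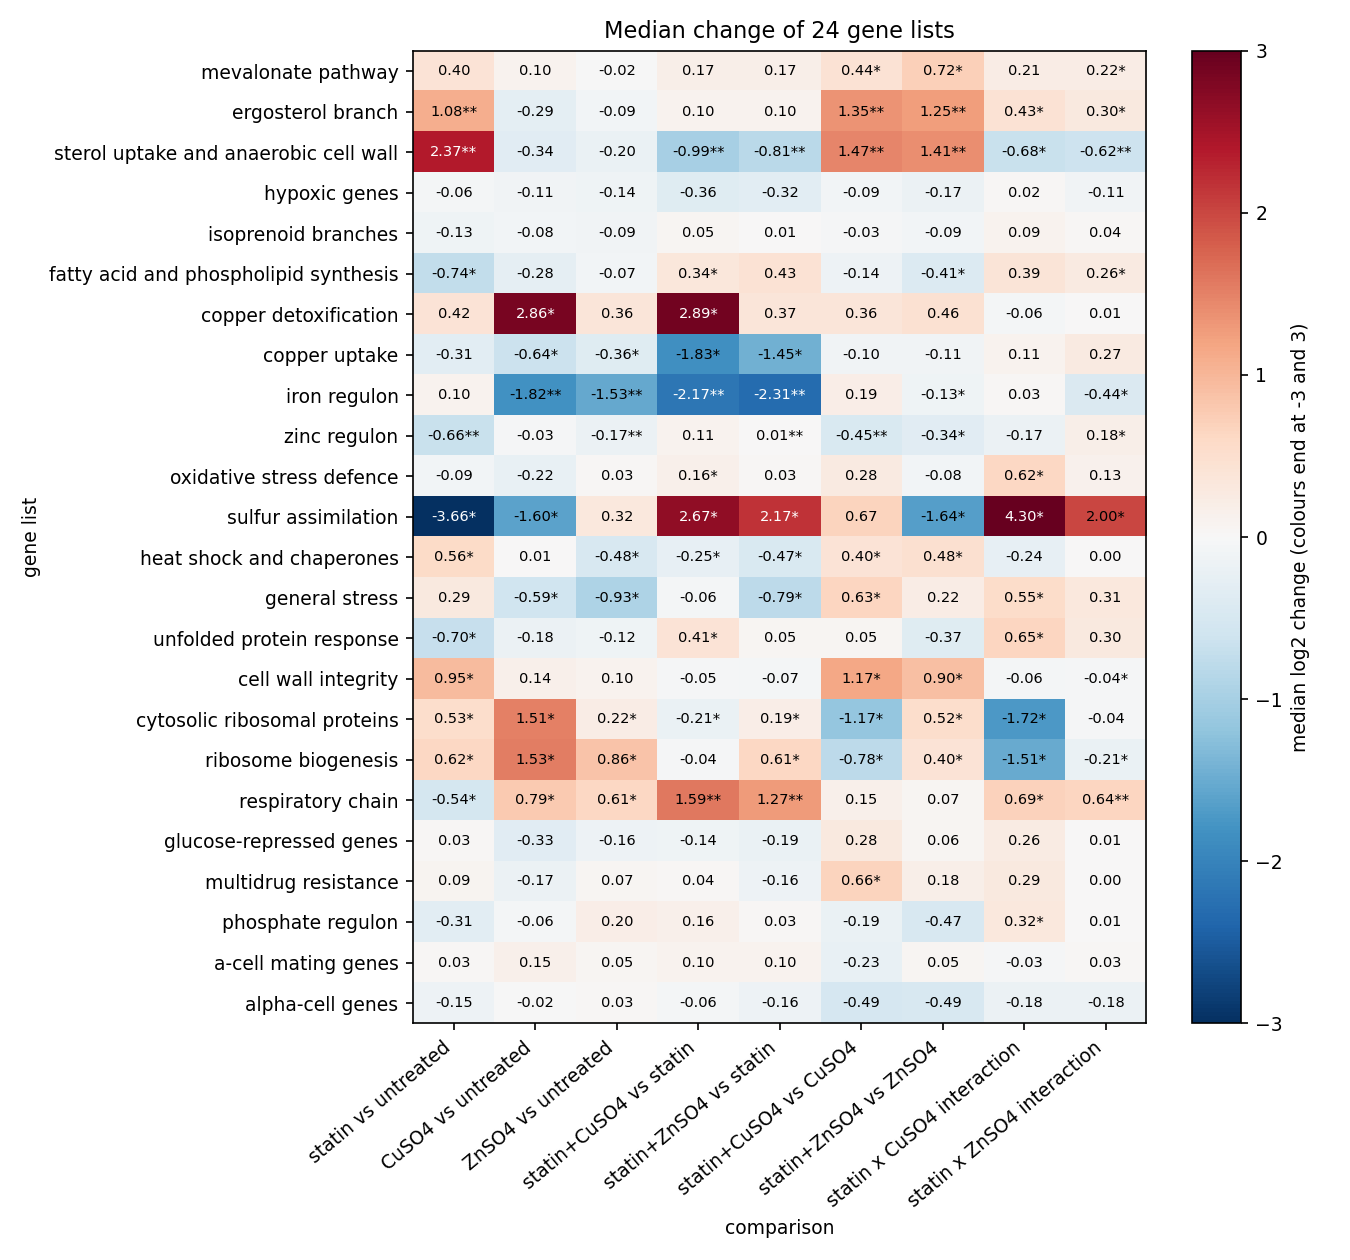
Median log2 change of each gene list in each comparison, with 1 asterisk for a camera adjusted p under 0.05 and 2 for lists that also pass with an estimated correlation. The ergosterol branch rose with statin in each background (1.08, 1.35 and 1.25), and iron regulon medians with an added metal lie between -2.31 and -1.53.

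The interactions asked whether each metal changed transcripts differently with statin than without it. Cultures with statin were collected at OD600 0.4 and those without at 0.8, so the statin and the density cannot be told apart here either. For CuSO4 the effect on AUS1 was lower with statin, with an interaction of -2.64 ± 0.19 (adjusted p = 2.1e-06), as was that on PDR11 (-1.14 ± 0.20). The effect on sterol synthesis went the other way, with 6 of 25 genes higher (9 adjusted over the list alone) and a median of 0.34 (adjusted p = 0.000599, adjusted p = 0.205 with an estimated correlation), led by ERG11, lanosterol demethylase, at 1.21 ± 0.26. Sulfur assimilation genes were higher in the interaction, 21 of 21 (21 adjusted over the list alone, median 4.30, adjusted p = 6.3e-15, adjusted p = 0.205 with an estimated correlation). Ribosomal protein genes were lower, 133 of 137 (136 adjusted over the list alone, median -1.72, adjusted p = 3.1e-57, adjusted p = 0.204 with an estimated correlation). The interaction of HMG1 was 0.34 ± 0.12 (adjusted p = 0.06, and 0.0313 with a replicate block; it passed without untreated replicate 2, 0.038, or statin with CuSO4 replicate 2, 0.0432). In all, 1033 genes passed, 455 higher and 578 lower.

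For ZnSO4, 58 genes passed, 37 higher and 21 lower, and 537 had an unadjusted p under 0.05. The count was 103 with a replicate block. It was 34, 32 or 28 without untreated replicate 1, 2 or 3, 35, 98 or 29 without statin replicate 1, 2 or 3, and 18 without statin with ZnSO4 replicate 3. The interaction of AUS1 was -2.26 ± 0.20 (adjusted p = 4.1e-05), and the arginine synthesis genes ARG1, ARG56 and ARG4 were higher by 3.08 ± 0.44, 2.35 ± 0.24 and 2.09 ± 0.33. These calls held with each sample left out. Sterol uptake and anaerobic cell wall genes had a median of -0.62 with 2 of 12 lower (5 adjusted over the list alone, adjusted p = 1.4e-07, adjusted p = 0.0382 with an estimated correlation). Respiratory chain genes had a median of 0.64 with 4 of 28 higher (16 adjusted over the list alone, adjusted p = 3.5e-21, adjusted p = 0.0382 with an estimated correlation).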

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

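The results here were singled out by a test of the difference itself, the interaction term of statin with each metal. The likeness of replicate 2 of statin with CuSO4 to that of statin with ZnSO4 was taken from the correlations between samples instead. Groups of 2 or 3 samples were not tested for a sample far from the others, and no signal in data outside the comparisons was found. The splits of the samples were planned, and all tests of the weighed patterns were chosen only after the results were seen.

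For CuSO4, 1033 genes passed. The effect of CuSO4 was higher with statin for MET3 (6.10 ± 1.38), SUL2 (6.08 ± 1.25), YCT1 (5.78 ± 1.01), PDC6 (5.57 ± 1.41) and MET10 (5.42 ± 1.13), and lower for the amino acid permeases TAT1 (-4.10 ± 0.56) and GNP1 (-3.04 ± 0.79), SPS100 (-3.81 ± 0.73) and the ribosomal protein gene RPL9A (-2.81 ± 0.51). Sterol uptake genes were lower, AUS1 at -2.64 and PDR11 at -1.14, as were the wall mannoprotein genes TIR4 at -1.45 and TIR1 at -0.95, while the ergosterol genes ERG11, ERG5, ERG25 and ERG3 were higher at 1.21, 1.19, 1.097 and 1.09. Of these, CuSO4 added to statin raised ERG11 (1.62) and ERG5 (0.87), but ERG25 (0.25) and ERG3 (-0.11) were not called. The interactions of ERG25 and ERG3 came mainly from falls with CuSO4 in the absence of statin (-0.85 and -1.20). FET3 and ZRT1 were lower at -0.94 (adjusted p = 0.016) and -0.95 (0.0083). Of the lists, sulfur assimilation had a median of 4.30, respiratory chain 0.69, oxidative stress defence 0.62, ergosterol branch 0.43, sterol synthesis 0.34, sterol uptake and anaerobic cell wall -0.68, ribosome biogenesis -1.51 and ribosomal proteins -1.72. These lists passed with adjusted p from 3.1e-57 to 0.00148, and none passed with an estimated correlation (adjusted p from 0.204 to 0.205). Called members, with those adjusted over the list alone in parentheses, numbered 16 of 28 (24) in the respiratory chain, 7 of 20 (10) in oxidative stress defence, 6 of 16 (7) in the ergosterol branch, 4 of 12 (6) in sterol uptake and anaerobic cell wall and 26 of 28 (28) in ribosome biogenesis.

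In the same interaction, general stress had a median of 0.55 (adjusted p = 0.00929; adjusted p = 0.593 with an estimated correlation), unfolded protein response 0.65 (0.0163; 0.531) and phosphate regulon 0.32 (0.0323; 0.33). General stress lost its call without statin replicate 2 (0.0502) or statin with CuSO4 replicate 1 (0.055), unfolded protein response without CuSO4 replicate 2 (0.0788) or statin with CuSO4 replicate 2 (0.159), and phosphate regulon without CuSO4 replicate 2 (0.0655), statin replicate 3 (0.0516) or statin with CuSO4 replicate 2 (0.0644). Called higher were 6 of 21 general stress genes with 1 lower (8 and 1 adjusted over the list alone), 0 of 11 of the unfolded protein response and 5 of 14 of the phosphate regulon (5 higher and 1 lower adjusted over the list alone). The phosphate regulon's median was 0.53 without CuSO4 replicate 3.

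For ZnSO4, 58 genes passed. Besides AUS1 (-2.26), the higher amino acid synthesis genes ARG1 (3.08), ARG56 (2.35), ARG4 (2.09) and LEU4 (2.07) and the lower iron transport genes ENB1 (-2.12) and FRE5 (-1.62) kept their calls with each sample left out, although FRE5 was well above background on only 2 arrays of its dimmest group. Other genes lost the call in some of the 11 fits without 1 sample: SAM3 (2.56) in 8, SPS100 (-3.46) in 10, the transporter PDR10 (-2.15) in 5, AAD10 (-2.00) in 9, PDR11 (-1.03) in 7, FIT3 (-1.73) in 9, and of the complex III genes RIP1 (1.03) in 2 and QCR10 (0.91), QCR6 (1.03) and QCR2 (0.91) in 9 each. Without statin with ZnSO4 replicate 3 their adjusted p ranged from 0.12 to 0.301, apart from AAD10, which passed there, and QCR2 also lost its call with a replicate block (0.0534). Of the lists, sulfur assimilation had a median of 2.00 (adjusted p = 7.1e-11; adjusted p = 0.311 with an estimated correlation), which was 3.03 and 1.04 without statin with ZnSO4 replicate 2 and 3. Respiratory chain at 0.64 and sterol uptake and anaerobic cell wall at -0.62 passed also with an estimated correlation (adjusted p = 0.0382 for both). Iron regulon at -0.44 (7.1e-11; 0.107 with an estimated correlation), ergosterol branch at 0.30 (0.000804; 0.188) and sterol synthesis at 0.28 (9.8e-05; 0.188) did not. Called members were 3 of 25 in the iron regulon (4 adjusted over the list alone) and 0 in sulfur assimilation (2), the ergosterol branch (4) and sterol synthesis (3). With a replicate block, ERG5 (adjusted p = 0.0198), ERG11 (0.0396), MET6 (0.026) and TIR4 (0.0445) passed too.

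The remaining lists of the ZnSO4 interaction depended on single samples and had 0 called members, except 1 of 15 in cell wall integrity; adjusted over the list alone these were 4 in fatty acid and phospholipid synthesis, 0 in mevalonate pathway, 2 in zinc regulon, 0 in ribosome biogenesis and 3 in cell wall integrity. Fatty acid and phospholipid synthesis at 0.26 (adjusted p = 0.015; adjusted p = 0.311 with an estimated correlation) lost its call without untreated replicate 3 (0.0618) or statin with ZnSO4 replicate 2 (0.145), and was 0.15 without statin replicate 1. Mevalonate pathway at 0.22 (0.0327; 0.311) lost it without untreated replicate 1 (0.059) or 3 (0.0618), ZnSO4 replicate 2 (0.0633), statin replicate 1 (0.108) or 3 (0.0503), or statin with ZnSO4 replicate 2 (0.342), and with a replicate block (0.0504); its median was 0.14 and 0.15 without statin replicate 1 and statin with ZnSO4 replicate 2. Zinc regulon at 0.18 (0.0327; 0.172) lost it without untreated replicate 3 (0.0911), ZnSO4 replicate 1 (0.0503), statin replicate 2 (0.0892) or statin with ZnSO4 replicate 2 (0.102), and was 0.28 without untreated replicate 2. Ribosome biogenesis at -0.21 (0.0178; 0.965) lost it without untreated replicate 3 (0.0622), ZnSO4 replicate 3 (-0.09, 0.69), statin replicate 2 (0.19) or 3 (0.0661), or statin with ZnSO4 replicate 2 (0.0868). Cell wall integrity at -0.0395 (0.0449; 0.654) lost it without untreated replicate 1 (0.0732) or 2 (0.169), ZnSO4 replicate 3 (0.105), statin replicate 2 (0.0846) or 3 (0.146), or statin with ZnSO4 replicate 2 (0.342), its median turning to 0.01 and 0.03 without untreated replicate 2 and statin with ZnSO4 replicate 2.

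Other splits of the samples gave fewer genes in each comparison of 3 against 3 samples, whose 10 splits are too few for a share under 0.05: only 1 split, the real one, reached the count of 2065 for statin against untreated, 1939 for CuSO4, 930 for ZnSO4, 939 for CuSO4 added to statin and 2486 for statin added to CuSO4, and the highest other was 0 in each. Where the numbers pair the samples, in the last 4, the real split is 1 of 4 that part as many pairs, and the highest other among these was also 0. For the CuSO4 interaction, 3 of 100 splits gave at least the real 1033 genes, and the highest other was 1750. The splits do not settle whether chance can be excluded there, and the bound set beforehand was a wrong one. All 11 other splits that kept untreated and CuSO4 samples as labelled gave 311 to 1750 genes, since the effect of CuSO4 without statin stays in them, while 78 of the remaining 88 gave 0. The 3 highest of these 11, at 1750, 1303 and 1012, put statin with CuSO4 replicates 2 and 3 with 1 statin sample on one side.

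Sulfur assimilation genes were lower with statin than without (median -3.66), but not when CuSO4 was present (0.67). With an estimated correlation, this list passed in no comparison. A lower harvest density of the statin cultures that acted alike in every background would give a fall in each. The lowest slide median of statin with CuSO4 against CuSO4 was -0.19, so density acting alike was not the whole cause. A median of -1.64 with ZnSO4 goes with it in part, and a density effect that differs with copper was not tested. Normalization of the arrays was argued against by an interaction median of at least 3.55 in 6 other settings, and the slide by at least 3.13 on each slide. Of these settings, the scanner's processed signals and the authors' value table are near duplicates. Either metal added to statin raised these genes, 19 of 21 with CuSO4 (median 2.67) and 16 of 21 with ZnSO4 (2.17), and statin with CuSO4 against statin with ZnSO4 had 0 of 21 called (0.28, adjusted p = 0.246). Without statin, CuSO4 lowered 7 of 21 (median -1.60) and ZnSO4 none (0.32), and CuSO4 against ZnSO4 had 10 of 21 lower (-2.07, adjusted p = 9.2e-09; adjusted p = 0.33 with an estimated correlation), so that the absent fall with CuSO4 rests in part on a baseline that CuSO4 had lowered, and how the metals act on these genes stays open.

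Replicate 2 of statin with CuSO4 correlated at r = 0.90 over genes with replicate 2 of statin with ZnSO4 and at 0.27 and 0.63 with its own group. A mislabelled sample was argued against by zinc transporter genes (ZRT1, ZRT2 and ZRT3), whose mean was 1.93 above the highest statin with ZnSO4 sample, and by CUP1 genes at 1.18 against at most -2.67 in samples without copper. A mix with statin with ZnSO4 would lower both means within the group. The zinc transporter mean was -0.14, against -0.36 and -0.12 in replicates 1 and 3, but CUP1 genes were the lowest of the group (1.18 against 2.03 and 1.48). Replicate 2 also had the lowest CUP1 mean in every other group (with CuSO4, 0.64 against 1.53 and 1.08). The low CUP1 value is therefore no sign of a mix, although a small share of other RNA is not excluded. A slide effect on all groups was argued against as the whole cause, because the slope of replicate 2 on this departure was at most 0.27 in untreated, CuSO4, ZnSO4 and statin. The slope of 0.50 in statin with ZnSO4 was taken against replicate 3 alone, not replicates 1 and 3, so it is not a like measure. Since r was 0.43 and 0.46 for CuSO4 and statin, a part may be shared. Another growth state of the replicate 2 cultures with statin and metal stays open: ribosomal protein genes were higher in replicate 2 than in the other replicates of the group by 0.32 with ZnSO4 (replicate 3 alone) and by 0.78 with CuSO4 (replicates 1 and 3). Other lists were split, with ribosome biogenesis at 0.72 for CuSO4 and -0.03 for ZnSO4 and general stress at -0.74 and -0.02, and sulfur assimilation was lower in both, at -2.55 and -1.99, and at -1.41 with CuSO4 alone.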

How the results depend on the processing

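No call reversed its direction: 0 of the named gene values (486, or 420 with the strict filter) and of the 216 list values turned past the threshold in the settings run for them or with any of 17 samples left out, although medians of called lists near 0 changed sign in some settings or without some samples (cell wall integrity and, on slides 1 and 2 only, ribosome biogenesis in the ZnSO4 interaction, zinc regulon for ZnSO4 added to statin), and ribosome biogenesis for CuSO4 added to statin, not called, passed upward or downward without 1 sample. With outlier-marked spots kept, every gene and list call held. By construction, Aquantile normalization, which leaves the log ratios as they are, and the brightest probe per gene gave the reported values, and the slide as a block gave those of the replicate block. An estimated correlation was run for lists and a 2-fold minimum for counts. Without 1 sample, 3197 of 3404 values of named genes kept their status, 179 calls were lost and 28 gained. Here and below, this total and that of 486 include named genes that were not called. Many named genes were picked for large changes or small adjusted p, which makes the share kept high. With the replicate block (the pairing of the samples by number), 469 of 486 held, 1 was lost and 16 gained, and it moved by over 1.5 times the count of the ZnSO4 interaction, to 103, and that of CuSO4 against ZnSO4, from 881 to 1420. No setting moved the median of all genes by over 0.1.

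Comparisons are in the order statin, CuSO4 and ZnSO4 against untreated, CuSO4 and ZnSO4 added to statin, statin added to CuSO4 and to ZnSO4, and the CuSO4 and ZnSO4 interactions. With the replicate block, 2641, 2510, 1361, 1378, 1575, 3055, 2075, 1459 and 103 genes were called. At least 2-fold changes numbered 434, 520, 167, 255, 326, 458, 320, 575 and 46, with overlaps of the metals of 105 without and 200 with statin, by the construction of that setting. On slides 1 and 2 only, a setting chosen after seeing the data that has fewer samples, the counts were 1102, 1256, 298, 421, 289, 1575, 486, 381 and 3, the overlaps 185 and 232, and 106 of 486 gene calls were lost; sterol synthesis then passed upward for ZnSO4 added to statin (0.24, adjusted p = 0.0143), as it did with scale normalization (0.18, 0.0214). With an estimated correlation, 3, 1, 2, 3, 4, 3, 2, 0 and 2 lists passed, and sterol synthesis no longer did for CuSO4 added to statin (0.12) and for the interactions (0.34 and 0.28), because a greater correlation widens the test's error. The sample channel alone gave 1281 for CuSO4, 571 for ZnSO4, 1039 for statin added to ZnSO4, 37 for the ZnSO4 interaction and an overlap of 421. Only the groups compared in the fit gave 570 for CuSO4 added to statin and an overlap of 454 with statin. Scale normalization gave 34 and an intensity trend with a robust prior 29 for the ZnSO4 interaction. Apart from the settings whose construction shows it, the cause was not tested.

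With single samples left out, ZnSO4 against untreated ranged from 610 (without untreated replicate 1) to 808. For CuSO4 added to statin, sterol synthesis ranged from 0.0568 (without statin replicate 1, adjusted p = 0.0743) to 0.23. For ZnSO4 added to statin, the count ranged from 564 to 1221 (moved without statin replicate 1, 817, and statin with ZnSO4 replicate 2, 759, and 3, 564) and sterol synthesis from 0.0689 to 0.21 (passing without statin replicate 2, 0.18, and statin with ZnSO4 replicate 3, 0.21). Statin added to ZnSO4 ranged from 719 to 1575 (moved without ZnSO4 replicate 1, 1025, and statin with ZnSO4 replicate 2, 1008, and 3, 719). The ZnSO4 interaction ranged from 18 (without statin with ZnSO4 replicate 3) to 98 (without statin replicate 2), with 34, 32 and 28 without untreated replicates 1, 2 and 3 and 35 and 29 without statin replicates 1 and 3, and its lists from 6 (without untreated replicate 3 or statin with ZnSO4 replicate 2) to 11. The overlap with statin ranged from 422 (without statin with ZnSO4 replicate 3) to 733. Where 1 statin with ZnSO4 sample was left, it was assumed to vary like the other groups. The third slide's lower signal over background limits genes near background.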

Other observations

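The comparisons of the metals with each other, and all tests of the hypothesis on iron, were chosen only after the results were seen.

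CuSO4 against ZnSO4 without statin gave 881 genes, 506 higher and 375 lower with CuSO4, and 1420 with a replicate block. ZRT1 was 31.4-fold higher with CuSO4 (4.97 ± 0.16, n = 3 per group, adjusted p = 3.1e-11), ZAP1, the transcription factor of the zinc regulon, was higher by 2.04 ± 0.19, and CUP1-1 by 4.76 ± 0.29. Ribosomal protein genes were higher with CuSO4, 130 of 137 (median 1.29, adjusted p = 6.4e-60; adjusted p = 0.181 with an estimated correlation), with RPL9A at 2.34 and RPL14A at 1.91. The sulfur uptake genes SUL1 and YCT1 were at -5.96 ± 0.99 and -4.62 ± 0.71. Sulfur assimilation genes were lower, 10 of 21 (median -2.07, adjusted p = 9.2e-09; adjusted p = 0.33 with an estimated correlation). Iron regulon genes were lower with CuSO4 than with ZnSO4, 16 of 25 with 1 higher (median -0.56, adjusted p = 1.4e-10; adjusted p = 0.161 with an estimated correlation), and zinc regulon genes higher, 7 of 13 with 1 lower (median 0.33, adjusted p = 3.8e-06; adjusted p = 0.00931 with an estimated correlation).

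With statin, 27 genes differed between CuSO4 and ZnSO4, 13 higher and 14 lower with CuSO4, 34 with a replicate block and 567 without statin with CuSO4 replicate 2. CUP1-1 was higher by 4.35 ± 0.33, ZRT1 by 3.03 ± 0.18, ZRT2 by 2.08 ± 0.18 and ZAP1 by 1.47 ± 0.21. The arginine and lysine synthesis genes named here were lower with CuSO4, ARG3 at -1.87 ± 0.30, LYS20 at -1.84 ± 0.29, ARG1 at -1.58 ± 0.33 and ARG56 at -1.18 ± 0.18. Ribosomal protein genes, higher with CuSO4 in the absence of statin, passed downward here as a list with 0 of 137 called (median -0.41, adjusted p = 8.9e-19, adjusted p = 0.42 with an estimated correlation). So did ribosome biogenesis with 0 of 28 (median -0.65, adjusted p = 8.9e-19, adjusted p = 0.175 with an estimated correlation). General stress was higher, 2 of 21 (0.84, 5.4e-18; 0.108), and so was the zinc regulon, 3 of 13 (0.19, 4.8e-06; 0.0111). The ergosterol branch did not pass (median 0.00, adjusted p = 0.801). Of the sterol uptake and anaerobic cell wall genes 0 of 12 were called, though that list passed downward (median -0.17, adjusted p = 0.0461, adjusted p = 0.42 with an estimated correlation).

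Iron regulon genes were lower with either metal, without and with statin. Normalization of the arrays was argued against by a median of -1.57 or lower in each of 6 other settings, and the slide by -1.42 or lower on each slide. Of these settings, the scanner's processed signals and the authors' value table are near duplicates. A candidate explanation is a greater supply of usable iron in the metal cultures, for example through metals that displace iron from EDTA in the medium, which asks that genes of iron-containing proteins be higher. The 17 such genes not named in any comparison had medians of 0.67 for CuSO4, 0.75 for ZnSO4, and 1.12 and 1.06 for each added to statin (camera p of 5.6e-07, 2.4e-09, 1.4e-10 and 1.3e-09, and with an estimated correlation p = 0.000219, 4.8e-05, 2.5e-05 and 4.2e-05). The list was, however, written after the results were seen, and 16 of its 33 members had been named. Of all 33 members, 24, 24, 26 and 27 were higher and 3, 1, 0 and 0 lower. The 3 with CuSO4 were ERG3, ERG5 and ERG25, all among the named members that the 17 leave out. No other cause of the lower iron regulon was tested on these genes, so their rise does not single out iron supply. Displacement of iron from EDTA was not tested. Faster growth of the metal cultures stays open: ribosomal protein medians in the 4 comparisons went down to -0.21, with slides at -0.65, 0.27 and -0.27 for CuSO4 added to statin.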
